A study of Mus musculus with 39 samples.

How the data were processed

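The data were single-cell RNA counts of sorted mouse progenitors in 39 libraries of 192 wells each, a library being 1 part of a plate, and a sample sheet with 1 entry per library. The libraries were made by MARS-seq, per the labels' protocols. The authors deposited whole-number counts per gene and well for all wells, with no normalization, as the values show. The values are called UMIs (counted transcripts) in the text because MARS-seq tags molecules, but the counting step, the aligner, the annotation and the genome build are not given in the sources used here. No coordinates are therefore reported. The deposited sheet, written by the authors, gave the sequencing run, Cre line, sort date, wells used or left empty, cells sorted, cells kept, sort gate, cell filter and number of embryos pooled, and 12 further columns of it were not used. Per the sheet, the authors kept cells with over 3000 genes and under 5% mitochondrial counts, and left out doublets and spike-ins. The deposited counts still held the wells that this filter leaves out.

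In 23 of the 39 files some gene names had been turned into dates, and these were set back to the names in the other files. The files shared 34307 genes. Spike-ins, which took 0.0725% of the counts in used wells, and the 2 YFP entries present in 20 libraries were left out of library sizes and tests. Of 7488 wells, the sheet listed 7089 as used (median 12033 UMIs) and 399 as empty (median 0, 90th percentile 1170). Of the wells listed empty, 64 held 500 or more UMIs. Used wells with 500 or more UMIs were kept as cells, 6554 in all. A replicate had 197 to 1463 cells. The stated filter, applied here without doublet removal, left 5148 cells, whereas the sheet counts 5002, and the numbers matched in 13 of 39 libraries, with a largest difference of 43 cells. By group, in the order E9.5 yolk sac, E10.5 yolk sac, E10.5 fetal liver and E12.5 fetal liver, it left 793, 1242, 1669 and 1444 cells, and the sheet counts 744, 1226, 1628 and 1404. No doublet caller was run here.

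The Rep number in the sample titles was taken as the replicate, and the counts of all cells of a replicate were summed over its libraries. Per the sheet a replicate was a pool of embryos, so p-values measure the spread between pools. Replicates were compared by a chi-square test of their summed counts over genes. E10.5 fetal liver replicates 5 and 6, sorted on the same date, were the closest pair (chi-square per gene 2.23, above sampling noise, compared with 8.45 to 34.7 for other pairs of a group) and were kept as 2 replicates. On the first 2 principal components of the summed counts (36.0% and 18.1% of the variance) E10.5 fetal liver replicate 3 and yolk sac replicate 5, both of sequencing run 2 with its low depth, were lowest on the second (-49.0 and -36.0). E9.5 replicate 1 of that run, at -10.6, lay among the liver replicates of run 3 (-15.9 to -9.75). Run 1 held E10.5 yolk sac replicates 1, 2 and 3, E10.5 fetal liver 1 and 2 and both E12.5 replicates. Run 2 held E9.5 replicate 1, E10.5 yolk sac replicate 5 and fetal liver replicate 3, and run 3 the rest. Stage and Cre line were confounded between E9.5 and E10.5.

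Summed counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, robust quasi-likelihood F test, group as the only term), with all 15 replicates in 1 fit and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The square root of the common dispersion was 0.248. Of the genes, 12256 had enough counts to be tested. CPM were scaled by TMM, and standard errors were the log2 fold change divided by the square root of F. In total 25 gene lists were fixed, and the 24 with 3 or more tested members were tested two-sided with camera of limma 3.58.1, with a preset correlation of 0.01 between genes and again with an estimated correlation. List members were matched by symbol, 10 of them through older symbols, such as Sfpi1 for Spi1, and Samd11, Hbb-bs and Hbb-bt were not matched. The gene lists, cell type markers, groups, tests, rule for named genes and first set of alternatives were fixed before the data were examined. The rule named, per comparison, the 10 largest rises and 10 largest falls among changed genes with a mean of 20 CPM or more in a group and no overlap between groups, up to 4 members of each described list with the smallest p, and the genes Kit, Csf1r, Gata1, Spi1, Pf4, Mpo, Hbb-bh1 and Hba-a1. Predicted genes and entries that join several names were counted but not named, and the text names a part of the genes the rule takes. Of these, 2 genes are not reported here. Lmo2, Mllt3, Tal1, Nfe2, Ppbp, Myl9 and Cald1 were named after their values were seen.

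Cells were clustered with scanpy 1.11.5 (Python 3.11.15). Genes in 20 or more cells were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes were chosen within replicates, values were limited to 10 SD, and 30 principal components with 15 neighbours gave a graph of shared neighbours. Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) used resolution 1 and a fixed seed. A cluster took a class name with 3 or more fixed markers of that class among its 50 leading genes by fold, 1 or more of them among the first 10, and more than of any other class. Clusters with 3 or more mitochondrial or ribosomal protein genes among the first 10 stayed unnamed. This naming rule, and the joining of hepatoblast and yolk sac endoderm markers into 1 endoderm-like class, were set after the clusters were seen. Shares of cells per class were compared between replicates by exact permutation tests, two-sided, adjusted over all classes and comparisons. Intervals on shares within 1 sample are 95% Wilson intervals, and intervals and limits from counts of 0 cover counting error only.

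The edgeR test and camera were tested on simulated counts of the same size, with 100 genes changed by 2-fold and 100 by 4-fold among 12256. For E10.5 fetal liver against E10.5 yolk sac, 55 and 86 were recovered with 6 false calls. For E10.5 against E9.5 yolk sac, 40 and 81 were recovered with 9 false calls, and for E12.5 against E10.5 fetal liver 50 and 84 with 3 false calls. None of the 20 lists without simulated change was called (0 of 20) in any of these. Simulated genes were drawn independently, so this cannot show how often camera falsely calls lists whose genes move together. The estimated correlation was 0.42 for the erythroid and 0.65 for the megakaryocyte list between the E10.5 tissues. The test within a class and the comparison of sorted wells were simulated only after they had been run on the data. For the sorted wells, 87 and 98 of 100 genes were recovered with 17 false calls among 11341.

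Alternatives were DESeq2 1.42.0, other scaling factors, no filter on low counts, minimums of 250 or 1000 UMIs per cell, thinning each cell to 500 UMIs, only the 2 groups in the fit, the replicate number as a block, sequencing run as a term, 1 Cre line, each replicate left out in turn, and other cluster resolutions (0.5 and 2) or clusters made without the changed genes. Added after the data were seen were the cell filter of the sheet, leaving out run 1, 2 or 3, run 1 alone, sort date as a block, only MEP or only non-MEP wells at E12.5, a looser naming of clusters, leaving out the endoderm-like cells, and a comparison of MEP with non-MEP wells.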

Results

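Erythro-myeloid progenitors, blood progenitors that form in the yolk sac and seed the fetal liver, were profiled as single cells from mouse embryos at E9.5, E10.5 and E12.5. Cells were sorted as Kit-positive and YFP-positive, leaving out cells with the surface markers Ter119, F4/80 or Gr1 of red cells, macrophages and granulocytes. YFP marked cells in which a Cre recombinase under the control of the Csf1r gene had been active, and their progeny. All E9.5 embryos carried the Csf1r-iCre line, and all other embryos carried the Csf1r-MeriCreMer line, whose recombinase is switched on by 4-hydroxytamoxifen, given at E8.5. Each well of a plate received 1 cell, and its polyadenylated RNA was read by MARS-seq, a plate-based single-cell method. The 39 libraries came from 15 replicates, with 2 of E9.5 yolk sac, 5 of E10.5 yolk sac, 6 of E10.5 fetal liver and 2 of E12.5 fetal liver. A replicate was a pool of YFP-positive embryos, per the deposited sample sheet. After removal of wells with fewer than 500 UMIs (counted transcripts), 6554 cells with 86167218 UMIs remained. These were 967 cells of E9.5 yolk sac, 1704 of E10.5 yolk sac, 2041 of E10.5 fetal liver and 1842 of E12.5 fetal liver. The median depth was 16829, 11795, 11815 and 12988 UMIs per cell in the same order. Replicates differed more, from a median of 1399 UMIs per cell in E10.5 yolk sac replicate 1 to 17698 in E12.5 fetal liver replicate 1. The counts summed over the cells of a replicate ranged from 2184418 to 17107585 UMIs. Of the 12256 genes tested, 2492 changed in at least 1 of the 3 comparisons. Levels are CPM of the summed counts, and log2FC is the fitted log2 fold change of the first group named over the second.

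The first comparison asked how progenitors of the same stage differed between the fetal liver and the yolk sac. At E10.5, 7 of 18 granulocyte, 2 of 7 mast cell and basophil, 3 of 8 lymphoid and 13 of 22 stem and multipotent progenitor genes fell in liver compared with yolk sac progenitors, while 3 of the stem and progenitor genes and 9 of 26 erythroid genes rose. The mast cell, lymphoid and stem lists also passed camera, a test of gene lists, with an estimated correlation between genes (adjusted p = 0.0307 for each), and the granulocyte and erythroid lists did not (adjusted p = 0.106 and 0.144 with an estimated correlation). Mpo, the myeloperoxidase of granulocyte granules, reached 284 ± 59.7 CPM against 1366 ± 108 (log2FC -2.27, SE 0.19, edgeR adjusted p = 1.51e-05), mean ± SD over 6 liver and 5 yolk sac replicates. Cd34, a surface protein of early progenitors, reached 29.6 ± 7.59 CPM against 153 ± 66.4 (log2FC -2.38, SE 0.28, edgeR adjusted p = 1.99e-04). In the other direction, Klf1, a transcription factor of red cell development, reached 520.2 ± 111 CPM against 291 ± 65.6 (log2FC 0.84, SE 0.18, edgeR adjusted p = 0.00967). In total 345 genes rose and 789 fell in liver. With scaling to library totals alone the split was 190 and 866.

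Of the granulocyte list, 0 of 18 tested members rose and 7 fell (0 and 10 adjusted over the list alone). The granulocyte list had a median log2FC of -1.63 and camera adjusted p = 1.94e-10 (adjusted p = 0.106 with an estimated correlation). Besides Mpo, it held Prtn3, a granule protease, with 111 ± 28 CPM against 585 ± 117 (log2FC -2.39, SE 0.28, edgeR adjusted p = 2.08e-04). Csf3r, the receptor of the granulocyte growth factor G-CSF, had 3.88 ± 1.43 CPM against 22.8 ± 6.80 (log2FC -2.57, SE 0.32, edgeR adjusted p = 1.76e-04). Of the mast cell and basophil list, 0 of 7 tested members rose and 2 fell (0 and 6 adjusted over the list alone). Its camera adjusted p was 1.87e-05 (adjusted p = 0.0307 with an estimated correlation). The members that fell were Hdc, which makes histamine, (log2FC -1.41, SE 0.16, edgeR adjusted p = 8.03e-05), and Cpa3, a mast cell protease, (log2FC -2.07, SE 0.51, edgeR adjusted p = 0.0220). Of the lymphoid list, 0 of 8 tested members rose and 3 fell (0 and 4 adjusted over the list alone). The lymphoid list had camera adjusted p = 2.86e-05 (adjusted p = 0.0307 with an estimated correlation). These were Satb1, a chromatin organiser, (log2FC -1.34, SE 0.17, edgeR adjusted p = 1.61e-04), and the B cell receptor genes Cd79b and Ighm (log2FC -1.25 and -2.09, edgeR adjusted p = 2.19e-04 and 0.00604). Of the macrophage and monocyte list, 0 of 27 tested members rose and 4 fell (0 and 4 adjusted over the list alone). Its camera adjusted p was 0.00495 (adjusted p = 0.564 with an estimated correlation). They included Fcer1g and Tyrobp, adaptors of immune receptors (log2FC -1.42 and -1.53, edgeR adjusted p = 2.68e-05 and 3.00e-04). Sfpi1, which encodes the myeloid transcription factor PU.1, fell as well, with 30.4 ± 12.4 CPM against 88.9 ± 13 (log2FC -1.55, SE 0.30, edgeR adjusted p = 0.00604).

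Of the stem and multipotent progenitor list, 3 of 22 tested members rose and 13 fell (3 and 15 adjusted over the list alone). The stem and progenitor list had camera adjusted p = 2.00e-12 (adjusted p = 0.0307 with an estimated correlation). Ptprc, which encodes the pan-leukocyte protein CD45, had 15.4 ± 4.26 CPM against 61.7 ± 11.8 (log2FC -2.02, SE 0.18, edgeR adjusted p = 1.51e-05). Erg, a transcription factor of blood stem cells, had 6.61 ± 1.73 CPM against 26.8 ± 6.39 (log2FC -2.03, SE 0.19, edgeR adjusted p = 1.90e-05). The 3 members that rose, named after their values were seen, were Lmo2, Mllt3 and Tal1 (log2FC 0.57, 0.47 and 0.36, edgeR adjusted p = 0.00377, 0.0450 and 0.0103). Of the megakaryocyte list, 0 of 26 tested members rose and 4 fell (0 and 9 adjusted over the list alone). The megakaryocyte list had camera adjusted p = 6.52e-05 (adjusted p = 0.418 with an estimated correlation). The largest of these falls was in Selp, the adhesion protein P-selectin, (log2FC -3.66, SE 0.48, edgeR adjusted p = 2.41e-04). Pf4, a platelet chemokine, varied widely between yolk sac replicates, with 63.4 ± 76.7 CPM against 634 ± 1321 (log2FC -3.32, SE 1.45, edgeR adjusted p = 0.191), and did not pass. Of the interferon response list, 0 of 17 tested members rose and 5 fell (0 and 7 adjusted over the list alone). The interferon list had camera adjusted p = 5.04e-04 (adjusted p = 0.116 with an estimated correlation). The proteasome subunit Psmb8 had the smallest p among them (log2FC -1.61, SE 0.19, edgeR adjusted p = 9.62e-05). Of the immediate early and stress list, 0 of 17 tested members rose and 3 fell (0 and 3 adjusted over the list alone). The immediate early list had camera adjusted p = 0.00361 (adjusted p = 0.359 with an estimated correlation). The members were Zfp36, Jun and Fos (log2FC -1.86, -1.01 and -1.51, edgeR adjusted p = 5.33e-04, 0.0243 and 0.0355). Of the Lin28b and fetal RNA-binding program list, 0 of 10 tested members rose and 3 fell (0 and 5 adjusted over the list alone). The RNA-binding program list had camera adjusted p = 0.00476 (adjusted p = 0.262 with an estimated correlation). They were Arid3a, Trim71 and Lin28a (log2FC -0.76, -1.62 and -2.13, edgeR adjusted p = 0.0137, 0.0105 and 0.0458). Without a small class of 16 endoderm-like cells, the call of Lin28a was lost (log2FC -1.95, edgeR adjusted p = 0.0795).

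Of the erythroid list, 9 of 26 tested members rose and 0 fell (12 and 0 adjusted over the list alone). The erythroid list had a median log2FC of 0.66 and camera adjusted p = 1.83e-10 (adjusted p = 0.144 with an estimated correlation). Epor, the erythropoietin receptor, had 122 ± 16.9 CPM against 75.1 ± 21.1 (log2FC 0.70, SE 0.17, edgeR adjusted p = 0.0159). Car2, a carbonic anhydrase of red cells, had 923 ± 147 CPM against 599 ± 58.9 (log2FC 0.62, SE 0.12, edgeR adjusted p = 0.00322). Gata1, a transcription factor of erythroid and megakaryocytic cells, had 336 ± 36.1 CPM against 242 ± 26.9 (log2FC 0.48, SE 0.13, edgeR adjusted p = 0.0269). Of the heme synthesis and iron uptake list, 7 of 18 tested members rose and 0 fell (10 and 0 adjusted over the list alone). The heme list had camera adjusted p = 5.20e-08 (adjusted p = 0.116 with an estimated correlation). Cpox and Alad, enzymes of heme synthesis, were among them (log2FC 0.95 and 0.79, edgeR adjusted p = 0.0172 and 0.00742). Of the glycolysis and hypoxia list, 4 of 22 tested members rose and 1 fell (5 and 1 adjusted over the list alone). The glycolysis list had camera adjusted p = 0.00955 (adjusted p = 0.418 with an estimated correlation). Slc2a1, a glucose transporter, and Vegfa, a growth factor of vessels, rose (log2FC 0.46 and 0.87, edgeR adjusted p = 0.0188 and 0.0221), and Egln3, an oxygen sensor, fell (log2FC -0.82, edgeR adjusted p = 0.00706). Among the largest rises were Slc38a5, an amino acid transporter, (log2FC 1.02, SE 0.17, edgeR adjusted p = 0.00131), and Kcnn4, a potassium channel, (log2FC 0.93, SE 0.19, edgeR adjusted p = 0.00626). Tnni3, cardiac troponin I, was another (log2FC 1.17, SE 0.20, edgeR adjusted p = 0.00209). The globins Hbb-bh1 and Hba-a1 did not pass, with log2FC of -0.71 and 0.17 (edgeR adjusted p = 0.301 and 0.916). Kit, the receptor used in the sort, was at 211 ± 26.1 CPM against 188 ± 13.5 (log2FC 0.17, SE 0.09, edgeR adjusted p = 0.290). Csf1r, the gene that drove Cre, was at 41 ± 40.6 CPM against 55.4 ± 25.5 (log2FC -0.45, SE 0.65, edgeR adjusted p = 0.777), and neither passed.

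The largest falls were in transcripts of yolk sac endoderm and liver cells. Afp, the fetal serum protein alpha-fetoprotein, had 2.33 ± 1.12 CPM against 233 ± 260.1 (log2FC -6.65, SE 1.04, edgeR adjusted p = 0.00201). Rbp4, the carrier of retinol, had 0.934 ± 0.666 CPM against 60.8 ± 62.5 (log2FC -5.93, SE 1.12, edgeR adjusted p = 0.00651). Of the hepatoblast list, 0 of 16 tested members rose and 12 fell (0 and 13 adjusted over the list alone). The hepatoblast list had camera adjusted p = 2.20e-09 (adjusted p = 0.126 with an estimated correlation). Of the yolk sac endoderm list, 0 of 14 tested members rose and 11 fell (0 and 13 adjusted over the list alone). The yolk sac endoderm list had camera adjusted p = 1.57e-08 (adjusted p = 0.146 with an estimated correlation). The spread between the yolk sac replicates was as large as the mean for these genes. Of the cells, 8 of the 1704 E10.5 yolk sac cells, but 0 of the 2041 E10.5 liver cells, fell into an endoderm-like class. A count of 0 cells there allows a share of up to 0.147%. With the 16 endoderm-like cells of all groups left out, the summed CPM of both lists was 113 ± 11.5 in liver and 171 ± 40.5 in yolk sac, compared with 822 ± 754 in yolk sac with them. Then 2 of 11 tested hepatoblast members fell (camera adjusted p = 0.0309, and adjusted p = 0.263 with an estimated correlation). In the same fit 2 of 7 yolk sac endoderm members fell (camera adjusted p = 0.112), and 990 genes changed in all. Without yolk sac replicate 1 the log2FC of Afp and Rbp4 was -5.82 and -5.33. Lists that did not pass were adult globins (0 of 4 members changed, camera adjusted p = 0.453), embryonic globins (0 of 4, 0.549) and cholesterol synthesis (0 of 18, 0.165). Nor did G2 and M phase (0 of 22, 0.688), S phase (0 of 24, 0.0846), mitochondrial transcripts (0 of 8, 0.294) or MHC class II (0 of 6, 0.0922) pass camera. The endothelial list had 1 rise and 3 falls among 15 (0.125), the imprinted and fetal growth list 1 and 1 among 14 (0.149), and the mesenchyme and mesothelium list 1 and 1 among 6 (0.677). Adjusted over the list alone, 4 imprinted, 4 mesenchyme and 2 MHC class II members fell, and the other counts of these lists were the same. Of the 1134 changed genes, 1134, 1076 and 1133 had the same direction within sequencing runs 1, 2 and 3 (2 against 3, 1 against 1 and 3 against 1 replicates), which is nearly fixed because these replicates took part in the call. Of the genes tested with all replicates and called without run 1, run 2 or run 3, tried after the data were seen, 203 of 203, 956 of 1136 and 84 of 85 had the same direction between the replicates of the run left out, compared with 69.2%, 55.6% and 67.9% of the genes not called. Leaving out 1 replicate ended the call of Mllt3 in 8 of 11 fits, of Fos, Gata1 and Lin28a in 7 each, of Cpa3, Jun and Vegfa in 4 each and of Slc2a1 in 1 (edgeR adjusted p up to 0.141). The count was 740 without yolk sac replicate 3, 64 within run 1 alone, 40 with each cell thinned to 500 UMIs and 1838 with the sort date as a block. The last rests on 3 liver and yolk sac pairs of a shared date.

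**Figure D1:**
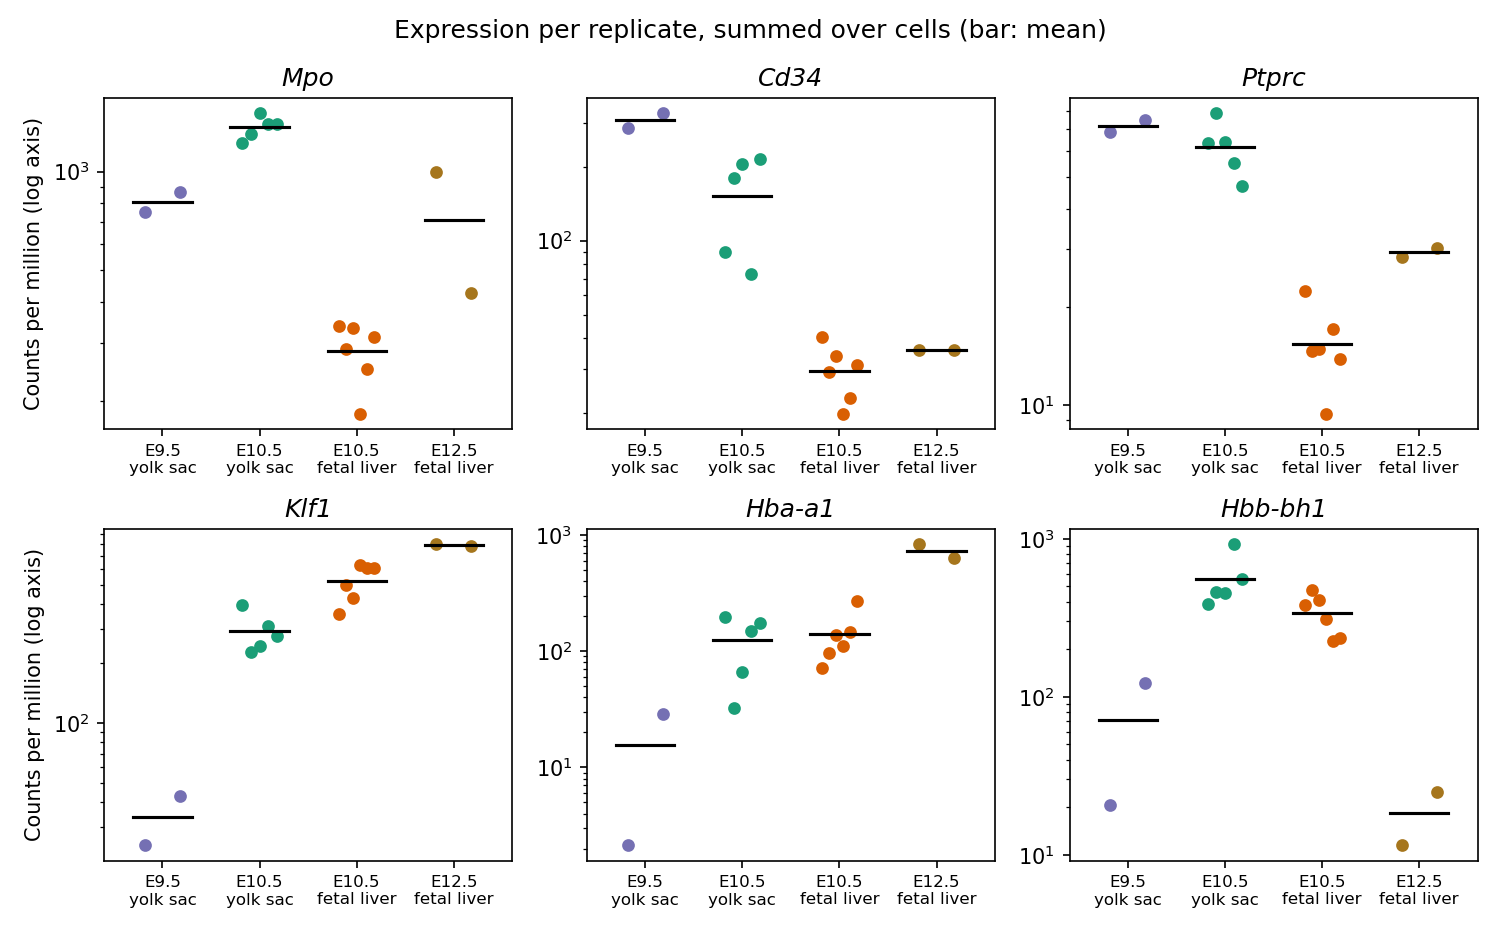
CPM (log axis) of 6 genes in the 15 replicates, as points by group, with the mean as a bar. Mpo, Cd34 and Ptprc averaged 284, 29.6 and 15.4 CPM in E10.5 fetal liver and 1366, 153 and 61.7 CPM in E10.5 yolk sac. Klf1 averaged 33.6 CPM at E9.5 and 291 CPM in E10.5 yolk sac. Hbb-bh1 averaged 339 CPM in E10.5 and 18.3 CPM in E12.5 fetal liver.

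The second comparison asked what changed in the yolk sac between E9.5 and E10.5. Of the tested members, 18 of 26 erythroid genes, 9 of 18 of heme synthesis and iron uptake, 2 of 4 adult globins, 1 of 4 embryonic globins and 1 of 7 mast cell and basophil genes, Hdc, rose. The erythroid list passed camera with an estimated correlation too (adjusted p = 0.0364), the heme, adult globin and mast cell lists did not (adjusted p = 0.0537, 0.0866 and 0.0537 with an estimated correlation), and the embryonic globin list passed neither test. Klf1 had 291 ± 65.6 CPM against 33.6 ± 13.3 (log2FC 3.08, SE 0.30, edgeR adjusted p = 6.06e-05), mean ± SD over 5 and 2 replicates. Slc38a5, the amino acid transporter, had 56.5 ± 11.2 CPM against 4.76 ± 2.21 (log2FC 3.40, SE 0.30, edgeR adjusted p = 1.28e-05), and a log2FC of 4.13 without E9.5 replicate 2. In the other direction, 3 of 15 endothelial genes fell and 1 rose, and 4 of 10 genes of the fetal RNA-binding program fell (adjusted p = 0.0941 for each list with an estimated correlation). Tie1, an endothelial receptor, had 14.2 ± 3.24 CPM against 58.3 ± 9.05 (log2FC -2.01, SE 0.35, edgeR adjusted p = 0.00315). In total 481 genes rose and 223 fell. Stage and Cre line changed together here, so the effects of both cannot be told apart.

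Of the erythroid list, 18 of 26 tested members rose and 0 fell (22 and 0 adjusted over the list alone). The erythroid list had a median log2FC of 2.57 and camera adjusted p = 6.08e-36 (adjusted p = 0.0364 with an estimated correlation). Car1, a carbonic anhydrase, had 62.8 ± 21.1 CPM against 1.86 ± 1.63 (log2FC 4.71, SE 0.51, edgeR adjusted p = 1.37e-04). Ermap, an erythroid membrane protein, had 135 ± 66.3 CPM against 6.52 ± 4.20 (log2FC 4.20, SE 0.51, edgeR adjusted p = 3.56e-04), and Epor had 75.1 ± 21.1 CPM against 12.6 ± 5.29 (log2FC 2.49, SE 0.28, edgeR adjusted p = 1.23e-04). Gata1 had 242 ± 26.9 CPM against 91.1 ± 32.8 (log2FC 1.39, SE 0.19, edgeR adjusted p = 3.71e-04). Of the heme synthesis and iron uptake list, 9 of 18 tested members rose and 0 fell (12 and 0 adjusted over the list alone). The heme list had camera adjusted p = 5.20e-13 (adjusted p = 0.0537 with an estimated correlation). Cpox had 369 ± 139.6 CPM against 80.6 ± 23.5 (log2FC 2.18, SE 0.35, edgeR adjusted p = 0.00186). Steap3, an iron reductase, rose too (log2FC 2.05, SE 0.27, edgeR adjusted p = 2.89e-04). Of the adult globin list, 2 of 4 tested members rose and 0 fell (3 and 0 adjusted over the list alone). The adult globin list had camera adjusted p = 1.09e-05 (adjusted p = 0.0866 with an estimated correlation). Hbb-b1 had 213 ± 191 CPM against 6.05 ± 2.03 (log2FC 5.04, SE 0.80, edgeR adjusted p = 0.00274), and Hbb-b2 had a log2FC of 2.71 (edgeR adjusted p = 0.0124). Reads of near-identical globin copies can be split between such genes. Among embryonic globins 1 of 4 members rose (1 adjusted over the list alone, camera adjusted p = 0.189), Hbb-bh1, with 557 ± 214 CPM against 71.6 ± 72.1 (log2FC 2.91, SE 0.64, edgeR adjusted p = 0.0169). Hba-a1 did not pass, with a log2FC of 2.81 (edgeR adjusted p = 0.0892). Pklr, the red cell pyruvate kinase, and Ank1, a protein of the red cell membrane skeleton, were among the 10 largest rises (log2FC 3.87 and 3.57, edgeR adjusted p = 0.0124 and 0.00281). Of the mast cell and basophil list, 1 of 7 tested members rose and 0 fell (2 and 0 adjusted over the list alone). Its camera adjusted p was 2.20e-04 (adjusted p = 0.0537 with an estimated correlation). Its member Hdc had 93.7 ± 25 CPM against 11 ± 1.01 (log2FC 3.07, SE 0.27, edgeR adjusted p = 1.28e-05). Without E10.5 replicate 1, Hbb-b1 averaged 128 CPM at E10.5, with a log2FC of 4.30, and Pklr had 3.18. Hbb-bh1 had a log2FC of 2.18 without E9.5 replicate 1 and 4.76 without E9.5 replicate 2. Without E9.5 replicate 2, Ank1, Car1, Epor, Ermap and Hbb-b2 had 5.80, 6.43, 3.08, 5.24 and 3.78.

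Of the endothelial list, 1 of 15 tested members rose and 3 fell (1 and 4 adjusted over the list alone). The endothelial list had camera adjusted p = 7.90e-04 (adjusted p = 0.0941 with an estimated correlation). Besides Tie1, Sox18, a transcription factor of vessels, and Eng, a receptor of the TGF-beta family, fell (log2FC -3.76 and -0.95, edgeR adjusted p = 0.00503 and 0.00997). Icam2, an adhesion protein, rose (log2FC 1.26, edgeR adjusted p = 0.00156). Flt1, a receptor of vascular growth factors, was among the 10 largest falls, with 5.98 ± 5.98 CPM against 52.2 ± 14 (log2FC -3.08, SE 0.79, edgeR adjusted p = 0.0368). So was Ttn, the muscle protein titin, with 3.08 ± 3.68 CPM against 44.4 ± 3.58 (log2FC -3.78, SE 0.69, edgeR adjusted p = 0.00503). Without E10.5 replicate 2 their log2FC was -3.89 and -4.88, and that of Sox18 was -2.71 without E9.5 replicate 1 and -4.42 without E9.5 replicate 2. Of the Lin28b and fetal RNA-binding program list, 0 of 10 tested members rose and 4 fell (0 and 4 adjusted over the list alone). The RNA-binding program list had camera adjusted p = 1.26e-05 (adjusted p = 0.0941 with an estimated correlation). Trim71, an RNA-binding protein of early development, had 5.23 ± 2.01 CPM against 29.8 ± 5.12 (log2FC -2.53, SE 0.39, edgeR adjusted p = 0.00112). Mycn, Hmga2 and Igf2bp2 had log2FC of -1.66, -1.58 and -0.72 (edgeR adjusted p = 0.0220, 0.0467 and 0.0482). Igf2, a fetal growth factor, had 58 ± 10.3 CPM against 283 ± 7.15 (log2FC -2.29, SE 0.59, edgeR adjusted p = 0.0395), and fell. Grb10, an adaptor of growth factor receptors, rose (log2FC 1.64, edgeR adjusted p = 1.23e-04). Their list, imprinted and fetal growth, did not pass (1 rise and 2 falls among 14, camera adjusted p = 0.955). The stem and multipotent progenitor list had 2 rises and 3 falls among 22 (camera adjusted p = 0.136), with a rise of Myb and a fall of Erg (log2FC 0.80 and -1.08, edgeR adjusted p = 0.00528 and 0.0106). Mpo, Sfpi1, Kit, Csf1r and Pf4 did not pass, with log2FC of 0.76, -1.21, 0.26, -0.09 and 3.82 (edgeR adjusted p = 0.128, 0.0828, 0.267, 0.969 and 0.425). Hoxb4, the only member of the Hox A and B list with enough counts, had a log2FC of -1.64 (edgeR adjusted p = 0.0340). In the first comparison it had -0.40 and in the third -1.43 (edgeR adjusted p = 0.598 and 0.10). That list was not tested.

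The granulocyte list had 1 rise and 1 fall among 18 (camera adjusted p = 0.492), and the macrophage and monocyte list 1 and 1 among 27 (0.420). Glycolysis and hypoxia had 2 and 2 among 22 (0.410). Cholesterol synthesis had 2 rises among 18 (0.522, with a median of -0.01 against an upward test). The megakaryocyte list had 1 rise among 26 (0.522), G2 and M phase 1 among 22 (0.808), and mesenchyme and mesothelium 2 rises and 2 falls among 6 (0.682). The lymphoid list had 1 fall among 8 (0.151) and the yolk sac endoderm list 1 rise among 14 (0.0510). Adjusted over the list alone, cholesterol synthesis had 3 rises and the stem list 4 falls, and the other counts of the lists that did not pass were the same. No member changed of S phase (24 tested, 0.0529), MHC class II (6, 0.136), hepatoblast (16, 0.189), immediate early and stress (17, 0.287), interferon response (17, 0.305) and mitochondrial transcripts (8, 0.522). Of the 704 genes, 703 had the same direction within run 2 and 704 within run 3 (1 replicate against 1 in each), which is nearly fixed because these replicates took part in the call. Of the genes tested with all replicates and called without run 2 or run 3, 243 of 249 and 158 of 159 had the same direction between the replicates of the run left out, compared with 60.3% and 66.2% of the genes not called. Without E9.5 replicate 1, 21 of the 35 called genes named in the text lost their call, among them Hbb-b1, Hbb-bh1, Cpox, Tie1, Sox18, Eng, Erg, Mycn and Icam2 (edgeR adjusted p 0.0543 to 0.304). Without E9.5 replicate 2, 9 did, among them Pklr and Myb (edgeR adjusted p = 0.157 and 0.117). Over the 7 fits without 1 replicate, Igf2 lost its call in 7, Fcer1g, Flt1, Hmga2 and Igf2bp2 in 6 each and Hoxb4 in 4. The count was 177 without E9.5 replicate 1, 296 without E9.5 replicate 2, 250 without the low-depth run 2, 303 with only these 2 groups in the fit and 48 with each cell thinned to 500 UMIs.

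The third comparison asked what changed in the fetal liver between E10.5 and E12.5. Of the tested members, 20 of 26 erythroid genes (1 fell), 4 of 4 adult globins, 12 of 18 granulocyte and 6 of 7 mast cell and basophil genes rose, and the embryonic globin Hbb-bh1 fell. The mast cell list passed camera with an estimated correlation too (adjusted p = 0.0245), and the erythroid, adult globin and granulocyte lists did not (adjusted p = 0.0608, 0.116 and 0.139 with an estimated correlation). Hbb-bh1 had 18.3 ± 9.62 CPM against 339 ± 98 (log2FC -4.19, SE 0.69, edgeR adjusted p = 0.00226), mean ± SD over 2 and 6 replicates. Hbb-b1 had 1176 ± 243 CPM against 250.01 ± 64.2 (log2FC 2.23, SE 0.49, edgeR adjusted p = 0.0121). Rhd, a blood group protein of the red cell membrane, had 253 ± 21.9 CPM against 25.7 ± 8.66 (log2FC 3.29, SE 0.43, edgeR adjusted p = 5.71e-04). Ctsg, the granule protease cathepsin G, had 92.2 ± 83.6 CPM against 2.18 ± 2.34 (log2FC 5.45, SE 0.78, edgeR adjusted p = 8.92e-04). Its log2FC was 3.95 without E12.5 replicate 1 and 6.17 without E12.5 replicate 2, and that of Hbb-bh1 was -4.88 without the latter. In total 679 genes rose and 647 fell with all E12.5 wells. The plates of E12.5 held wells sorted as MEP (megakaryocyte-erythroid progenitors) and wells sorted as non-MEP, a split that the E10.5 plates did not have. With only the MEP wells 953 genes rose and 1739 fell, and with only the non-MEP wells 699 rose and 344 fell. With only the MEP wells at E12.5, 0 of the 22 tested granulocyte and mast cell genes rose and 7 fell, with a median log2FC of -1.76.

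Of the erythroid list, 20 of 26 tested members rose and 1 fell (23 and 1 adjusted over the list alone). The erythroid list had a median log2FC of 1.52 and camera adjusted p = 6.76e-20 (adjusted p = 0.0608 with an estimated correlation). Tspo2, a cholesterol carrier of erythroblasts, had 78.7 ± 2.18 CPM against 8.05 ± 3.03 (log2FC 3.29, SE 0.39, edgeR adjusted p = 2.41e-04). Hemgn, a nuclear protein of erythroid cells, had 222 ± 22.2 CPM against 31 ± 9.72 (log2FC 2.83, SE 0.38, edgeR adjusted p = 6.48e-04). The 1 member that fell, named after its value was seen, was Nfe2 (log2FC -1.03, edgeR adjusted p = 0.00118). Gata1 did not pass (log2FC -0.20, edgeR adjusted p = 0.541). Of the heme synthesis and iron uptake list, 11 of 18 tested members rose and 0 fell (13 and 0 adjusted over the list alone). The heme list had camera adjusted p = 7.11e-12 (adjusted p = 0.0608 with an estimated correlation). Uros, an enzyme of heme synthesis, had 95.3 ± 5.86 CPM against 28.8 ± 1.66 (log2FC 1.72, SE 0.13, edgeR adjusted p = 6.36e-06). Fech, another, had 390.0 ± 14.7 CPM against 199 ± 39.8 (log2FC 0.97, SE 0.19, edgeR adjusted p = 0.00370). Of the adult globin list, 4 of 4 tested members rose and 0 fell (4 and 0 adjusted over the list alone). The adult globin list had camera adjusted p = 5.54e-05 (adjusted p = 0.116 with an estimated correlation). Hba-a1 had 729 ± 141 CPM against 139 ± 69.6 (log2FC 2.39, SE 0.64, edgeR adjusted p = 0.0333). Of the embryonic globin list, 0 of 4 tested members rose and 1 fell (0 and 2 adjusted over the list alone). The embryonic globin list had camera adjusted p = 0.00422 (adjusted p = 0.164 with an estimated correlation). Of the cholesterol synthesis list, 4 of 18 tested members rose and 0 fell (5 and 1 adjusted over the list alone). The cholesterol list had camera adjusted p = 2.89e-04 (adjusted p = 0.0608 with an estimated correlation). With only the MEP wells or only the non-MEP wells at E12.5, the median of the erythroid list was 1.66 and 1.30.

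Of the granulocyte list, 12 of 18 tested members rose and 0 fell (13 and 1 adjusted over the list alone). The granulocyte list had a median log2FC of 2.67 and camera adjusted p = 6.73e-08 (adjusted p = 0.139 with an estimated correlation). Mpo had 712 ± 403 CPM against 284 ± 59.7 (log2FC 1.32, SE 0.24, edgeR adjusted p = 0.00243). Elane, neutrophil elastase, had 60 ± 68.9 CPM against 3.17 ± 3.37 (log2FC 4.28, SE 0.81, edgeR adjusted p = 0.00493). Of the mast cell and basophil list, 6 of 7 tested members rose and 0 fell (6 and 0 adjusted over the list alone). Its camera adjusted p was 1.58e-07 (adjusted p = 0.0245 with an estimated correlation). Gzmb, the protease granzyme B, had 22.2 ± 0.995 CPM against 0.684 ± 1.20 (log2FC 5.10, SE 0.87, edgeR adjusted p = 0.00238). Cpa3 had 25.7 ± 17.5 CPM against 5.14 ± 3.15 (log2FC 2.34, SE 0.60, edgeR adjusted p = 0.0234). The median over the tested members of both lists was 2.42 with all wells, 3.68 with only the non-MEP wells and -1.76 with only the MEP wells. With the MEP wells alone the direction of Mpo, Elane and Cpa3 turned (log2FC -2.57, -1.23 and -2.52). Without E12.5 replicate 1, Mpo and Elane had a log2FC of 0.59 and 1.86, and without E12.5 replicate 2, Elane and Cpa3 had 5.15 and 1.38. Without E10.5 replicate 1, Elane and Gzmb had 5.01 and 6.72. Of the MHC class II list, 3 of 6 tested members rose and 0 fell (5 and 0 adjusted over the list alone). The MHC class II list had camera adjusted p = 1.57e-04 (adjusted p = 0.164 with an estimated correlation). Its member H2-Ab1 had 62.6 ± 15 CPM against 9.98 ± 5.60 (log2FC 2.63, SE 0.55, edgeR adjusted p = 0.00780). The summed CPM of that list was 319 and 206 in the E12.5 replicates, 91.2 and 57.2 in E10.5 liver replicates 1 and 2, and 8.28 to 10.47 in the other E10.5 liver replicates. Within sequencing run 1 its median log2FC was 2.0 (camera adjusted p = 8.13e-05, and adjusted p = 0.265 with an estimated correlation). Of the hepatoblast list, 5 of 16 tested members rose and 1 fell (8 and 1 adjusted over the list alone). The hepatoblast list had camera adjusted p = 2.89e-04 (adjusted p = 0.283 with an estimated correlation). Alb, serum albumin, had 38.8 ± 10.9 CPM against 1.02 ± 1.20 (log2FC 5.23, SE 0.90, edgeR adjusted p = 0.00259), and a log2FC of 6.02 without E10.5 replicate 6. Without the 2 endoderm-like cells of E12.5 and those of the other groups, 2 of 11 tested members rose and 1 fell (camera adjusted p = 0.299).

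Of the glycolysis and hypoxia list, 0 of 22 tested members rose and 8 fell (1 and 10 adjusted over the list alone). The glycolysis list had camera adjusted p = 1.14e-07 (adjusted p = 0.117 with an estimated correlation). Among them Egln3 had 11.3 ± 1.15 CPM against 39 ± 7.62 (log2FC -1.78, SE 0.26, edgeR adjusted p = 6.27e-04). Slc2a1 fell too (log2FC -1.07, SE 0.16, edgeR adjusted p = 7.56e-04). Of the megakaryocyte list, 0 of 26 tested members rose and 7 fell (0 and 8 adjusted over the list alone). The megakaryocyte list had camera adjusted p = 8.26e-06 (adjusted p = 0.374 with an estimated correlation). Itga2b, the platelet integrin CD41, had 30.8 ± 0.699 CPM against 145 ± 20.8 (log2FC -2.23, SE 0.27, edgeR adjusted p = 2.41e-04). Of the Lin28b and fetal RNA-binding program list, 0 of 10 tested members rose and 3 fell (0 and 7 adjusted over the list alone). The RNA-binding program list had camera adjusted p = 4.00e-06 (adjusted p = 0.110 with an estimated correlation). Igf2bp2, an RNA-binding protein, had 14 ± 2.66 CPM against 81.8 ± 14.6 (log2FC -2.53, SE 0.24, edgeR adjusted p = 4.58e-05). Of the endothelial list, 0 of 15 tested members rose and 4 fell (0 and 4 adjusted over the list alone). The endothelial list had camera adjusted p = 0.0120 (adjusted p = 0.164 with an estimated correlation). The receptor Tek had the smallest p among them (log2FC -2.21, SE 0.30, edgeR adjusted p = 4.09e-04). Tnni1, slow skeletal troponin I, was among the 10 largest falls, with 4.25 ± 0.948 CPM against 53.8 ± 3.91 (log2FC -3.62, SE 0.47, edgeR adjusted p = 4.58e-04). Kit, Sfpi1, Csf1r and Pf4 did not pass, with log2FC of 0.03, -0.09, -1.62 and -0.00 (edgeR adjusted p = 0.924, 0.927, 0.350 and 0.999). Lists that did not pass were the stem and multipotent progenitor list (2 rises and 4 falls among 22, camera adjusted p = 0.624, with a median of 0.04 and a mean of -0.02) and imprinted and fetal growth (3 and 1 among 14, 0.258). Neither did interferon response (2 and 1 among 17, 0.112), lymphoid (1 and 1 among 8, 0.587) or S phase (2 and 0 among 24, 0.201). The same held for immediate early and stress (0 and 1 among 17, 0.292), macrophage and monocyte (0 and 1 among 27, 0.112), and yolk sac endoderm (0 and 1 among 14, 0.258). No member changed of G2 and M phase (0 of 22, 0.258), mesenchyme and mesothelium (0 of 6, 0.286) and mitochondrial transcripts (0 of 8, 0.587). Adjusted over the list alone, the imprinted list had 4 rises, interferon response 3 rises, the stem list 5 falls and yolk sac endoderm 0 falls, and the other counts of these lists were the same. Of the 1326 genes, 1326 had the same direction within run 1 (2 against 2 replicates), the only run with both groups, which is nearly fixed because these replicates, among them both of E12.5, took part in the call. Without E12.5 replicate 1, 15 of the 32 called genes named in the text lost their call, among them Hbb-bh1, Hbb-b1, Mpo, Elane and H2-Ab1 (edgeR adjusted p 0.0587 to 0.379). Without E12.5 replicate 2, 10 did, among them Fech and Cpa3 (edgeR adjusted p = 0.0554 and 0.408), and Hba-a1 lost its call in 7 of 8 fits without 1 replicate. The count was 289 without E12.5 replicate 1, 512 without E12.5 replicate 2, 2692 with only the MEP wells, 477 within run 1 and 93 with each cell thinned to 500 UMIs.

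Gene lists were also tested with only the MEP or only the non-MEP wells at E12.5, tried after the data were seen. E10.5 had no such gate, so where MEP and non-MEP wells differ, gate and stage cannot be told apart. Within E12.5, MEP against non-MEP wells gave megakaryocyte and stem medians of -2.47 and -2.85. Of 26 megakaryocyte members, 14 fell with the MEP wells (16 adjusted over the list alone), with a median log2FC of -2.45 (camera adjusted p = 2.00e-08, and adjusted p = 0.259 with an estimated correlation). With the non-MEP wells 1 fell (1 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.0305, and adjusted p = 0.679 with an estimated correlation). Of the stem and multipotent progenitor list, 1 of 22 members rose and 17 fell with the MEP wells (2 and 17 adjusted over the list alone), with a median of -1.69 (camera adjusted p = 2.59e-08, and adjusted p = 0.0563 with an estimated correlation). With the non-MEP wells 8 of 23 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 1.81e-04, and adjusted p = 0.115 with an estimated correlation). Of the endothelial list, 6 of 13 members fell with the MEP wells (7 adjusted over the list alone), with a median of -2.52 (camera adjusted p = 9.12e-06, and adjusted p = 0.0489 with an estimated correlation). With the non-MEP wells 1 of 15 rose and 2 fell (2 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.585). Of the hepatoblast list, 9 of 18 members rose and 0 fell with the non-MEP wells (14 and 1 adjusted over the list alone, camera adjusted p = 3.58e-10, and adjusted p = 0.101 with an estimated correlation). With the MEP wells 2 of 16 fell (camera adjusted p = 0.981). With the MEP wells, 8 of 27 macrophage and monocyte members and 3 of 6 lymphoid members fell, and 7 of 24 of S phase rose (10, 3 and 7 adjusted over the list alone, camera adjusted p = 2.50e-06, 0.0267 and 0.00455, and adjusted p = 0.349, 0.259 and 0.0563 with an estimated correlation). With the non-MEP wells 6 of 28 macrophage and monocyte members rose and 0 fell (6 and 1 adjusted over the list alone), with a median of -0.68 against an upward test, and the list did not pass (camera adjusted p = 0.383). With the non-MEP wells, 4 of 16 imprinted and fetal growth, 3 of 17 interferon response, 2 of 7 lymphoid and 2 of 7 mesenchyme and mesothelium members rose (8, 5, 3 and 2 adjusted over the list alone, where 1 imprinted member fell). These lists passed camera (adjusted p = 0.00306, 1.74e-04, 0.00554 and 0.0305, and adjusted p = 0.275, 0.101, 0.101 and 0.161 with an estimated correlation). The embryonic globin list did not pass with the MEP wells (1 of 4 fell, camera adjusted p = 0.0713). Of 18 members of heme synthesis and iron uptake, 13 rose with the MEP and 5 with the non-MEP wells (15 and 10 adjusted over the list alone, adjusted p = 0.0563 and 0.128 with an estimated correlation). Of 10 members of the RNA-binding program, 7 and 2 fell (8 and 2 adjusted over the list alone, adjusted p = 0.0833 and 0.161 with an estimated correlation).

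**Figure D2:**
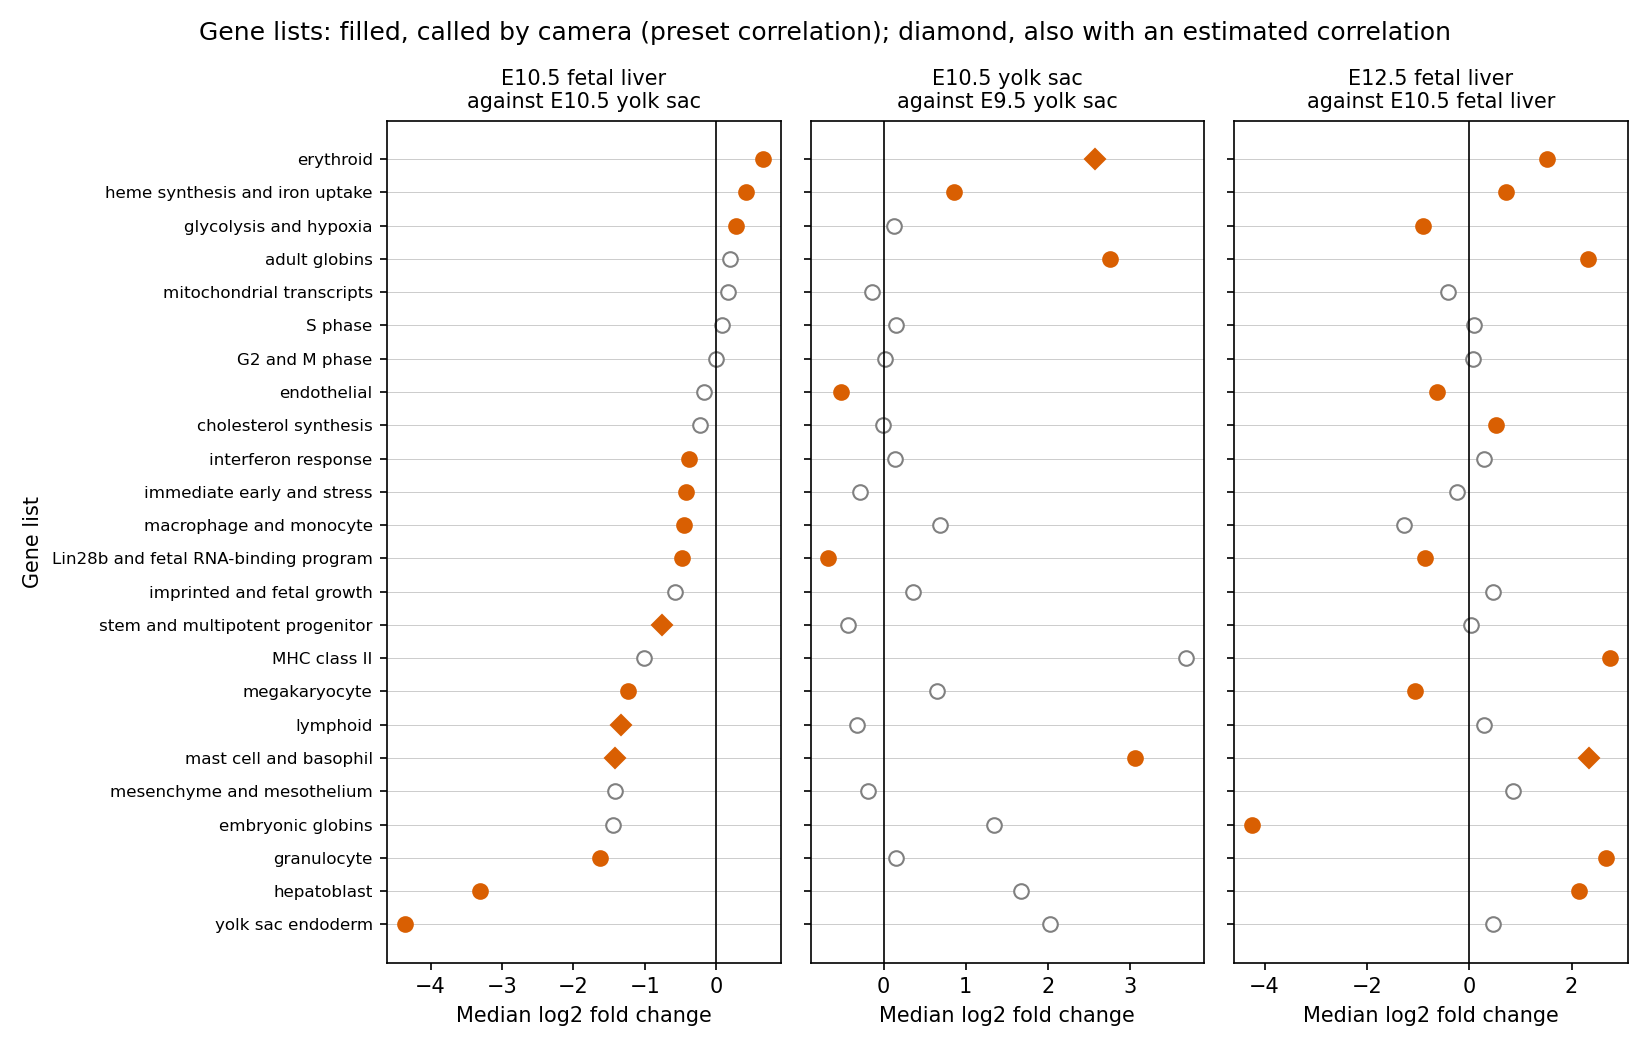
Median log2 fold change of the tested members of 24 gene lists in the 3 comparisons. Filled points passed camera with a preset correlation and diamonds also with an estimated one. The erythroid list had medians of 0.66, 2.57 and 1.52, and the granulocyte list -1.63, 0.15 and 2.67.

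**Figure D3:**
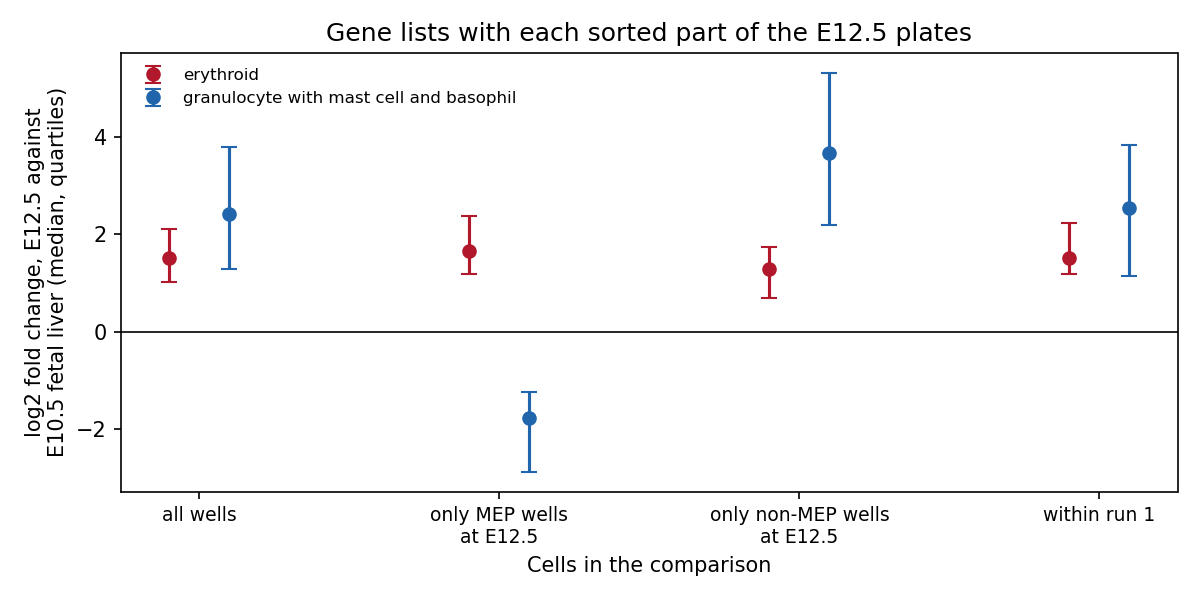
Median log2 fold change between E12.5 and E10.5 fetal liver (points, with quartiles as bars) of the erythroid list and of the granulocyte with the mast cell and basophil list, by the cells used. With only the MEP wells the erythroid median was 1.66 and the other median was -1.76.

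Cells were grouped into 16 clusters, of which 7 carried a cell type name from fixed markers and 9 carried none. The named classes were erythroid-like (1070 cells), megakaryocyte-like (503), granulocyte-like (362), mast cell-like (247), macrophage-like (63) and endoderm-like (16). Unnamed clusters held 85.7% of E10.5 liver, 71.2% of E10.5 yolk sac, 26.7% of E12.5 liver and 86.8% of E9.5 yolk sac cells. The largest were a cluster led by Parm1, Muc13 and Ass1 (29.6% of E10.5 liver and 13% of E10.5 yolk sac cells) and a cluster led by the embryonic globins Hba-x, Hbb-y and Hbb-bh1 (29.5% and 6.69%). A further one was led by Igf2, Serpina3g and Flt1 (58.4% of E9.5 yolk sac cells). None of the 18 class by comparison tests passed the Benjamini-Hochberg adjustment (exact permutation, two-sided). The smallest p the design allows is 0.0952 for 5 against 2 replicates and 0.0714 for 6 against 2. Erythroid-like cells made up 60.8% ± 10.6 of E12.5 liver cells (SD, n = 2) and 0.768% ± 0.677 of E10.5 liver cells (n = 6, exact p = 0.0714, adjusted p = 0.214). With clusters made without the 2492 changed genes the shares were 59% ± 11 and 10.47% ± 11.1 (exact p = 0.0714). With a looser naming rule, under which 3 more clusters counted as erythroid-like, the shares were 71.3% ± 1.05 and 29.2% ± 17.3 (n = 2 and 6, exact p = 0.0714), and both rules were set after the clusters were seen. Granulocyte-like cells made up 1.88% ± 2.15 of E10.5 liver cells (n = 6) and 12.3% ± 8.88 of E10.5 yolk sac cells (n = 5, exact p = 0.0390, adjusted p = 0.214). Clustered without the changed genes, these were 0.574% ± 0.807 and 2.02% ± 2.09 (exact p = 0.139). With the cell filter stated in the sheet, tried after the data were seen, the share at E10.5 was 1.62% ± 1.52 in liver and 14.9% ± 5.47 in yolk sac (n = 6 and 5, exact permutation adjusted p = 0.0390). With that filter mast cell-like cells made up 8.04% ± 1.91 of E10.5 liver and 21% ± 3.59 of E10.5 yolk sac cells (exact permutation adjusted p = 0.0390). The class then took in a cluster of 388 cells led by Csf2rb, Hdc and Lmo4, and the cluster led by these genes in the reported clustering, of 609 cells, had no name. In the reported clustering the mast cell-like shares at E10.5 were 1.01% ± 0.691 in liver and 1.48% ± 1.0 in yolk sac (n = 6 and 5, exact p = 0.437, adjusted p = 0.562). Mast cell-like cells made up 9.93% ± 2.10 of E12.5 and 1.01% ± 0.691 of E10.5 liver cells (n = 2 and 6, exact p = 0.0714). Without the changed genes these were 9.73% ± 2.19 and 0.861% ± 0.596 (exact p = 0.0714). Shares of E12.5 cells follow the number of wells sorted as MEP and as non-MEP.

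Changes within a class were tested where at least 2 replicates per group had 10 or more cells, which left the megakaryocyte-like class at E10.5. It had 168 liver cells of 6 replicates and 187 yolk sac cells of 3. No gene of 8576 changed between these tissues within that class by edgeR at an adjusted p under 0.05. Of these, 475 had an unadjusted p under that value, where chance gives a share of about 0.05, and DESeq2 also called 0 genes. With sort date as a block, tried after the data were seen, the test rested on 3 liver and yolk sac pairs of a shared date. By it 3 genes fell in liver, named after their values were seen. They were Ppbp, a platelet chemokine, Myl9, a myosin light chain, and Cald1, an actin-binding protein (log2FC -4.45, -5.58 and -2.83, edgeR adjusted p = 1.05e-07, 1.46e-05 and 0.0395). Over the 3 yolk sac replicates they had 689 ± 1189.5, 117 ± 199.7 and 95.4 ± 149 CPM, and over the 6 liver replicates 14.9 ± 35.7, 1.13 ± 2.76 and 7.87 ± 7.73 CPM. Of the 2 clusters of the class, the smaller, with 52 cells, took 92.3% of them from yolk sac replicate 3. In simulated counts of that size, edgeR recovered 30 of 100 genes changed by 2-fold and 85 of 100 changed by 4-fold, with 9 false calls.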

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

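The tests of MHC class II transcripts were set before their values were seen, though the pattern had been noticed in the clusters, and no other explanation is tested in this part. The highest or lowest replicate was compared with its nearest neighbour (Dixon's test at 95%) for 173 measures in the 2 groups of 5 and 6 replicates, and 20 stood apart. Chance gives about 1 in 20 of the measures tested, or 8.65 of the 173. In E10.5 yolk sac replicate 1, erythroid genes were high. Hbb-b1 reached 554 CPM (next highest replicate 150.1), Ermap 251.9 CPM (118), Fech 169.5 CPM (132), Epor 112 CPM (70.9) and Pklr 100.5 CPM (35.6). Steap3 reached 54.7 CPM (33), Rhd 42.4 CPM (15.4), Uros 32.4 CPM (24.8) and the megakaryocyte gene Selp 11.5 CPM (6.31). Macrophage-like cells made up 2.39% of that replicate (next highest 0.533%). In E10.5 yolk sac replicate 3, the platelet gene Pf4 reached 2997 CPM (next 89). In replicate 2, Flt1 reached 16.4 CPM (5.17) and Ttn 9.61 CPM (2.08). In E10.5 fetal liver replicate 1, megakaryocyte-like cells made up 18.1% (next 9.02%), and Arid3a was at 155 CPM (99.6), Trim71 at 3.63 CPM (1.78) and Gzmb at 3.07 CPM (0.740). H2-Ab1 was at 21.4 CPM in fetal liver replicate 2 (8.38), Hba-a1 at 270.01 CPM in replicate 6 (145) and Rhd at 8.92 CPM in replicate 3, where the next lowest was 26.8.

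Counts of the YFP entries, which no comparison used, were present in the cells of run 1. They held 38824 UMIs of YFP-plus and 41 of YFP-minus, the names that the files use. YFP-plus made up 777 to 965 CPM in the 7 replicates, and 73.7% to 99.6% of cells had at least 1. The lowest share of cells was in E10.5 yolk sac replicate 1. In 146 wells listed as empty, 168 YFP-plus and 0 YFP-minus UMIs were counted, and 52.1% of those wells had YFP-plus.

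MHC class II transcripts, of antigen-presenting cells, took 34.7 of 10000 UMIs in the 255 wells of E10.5 yolk sac replicate 1 with fewer than 2000 UMIs and 0.990 in the 103 wells with 5000 or more. Against a few cells of another type, the 5% of wells with the most of these transcripts held 17.6% of them. In UMIs per well the shallow and deep wells were close, at 4.05 ± 0.231 and 3.19 ± 0.281 (SE over wells), a ratio of 0.789, and 84.6% of the wells of all depths had at least 1, which is consistent with a background shared by all wells. The list's CPM in the E10.5 yolk sac replicates was 381, 267, 40.6, 10.53 and 8.28, with the 3 highest all in run 1, so a background of that run may add to the rise of this list at E12.5, whose replicates were all in run 1. Where such a background would come from stays open, and no biological explanation was tested.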

How the results depend on the processing

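The alternatives chosen after the data were seen were those listed so with the processing and all fits of the sorted wells against each other. Counts of genes, of lists and of classes stayed within 1.5 times of the reported value in 126 results and moved more in 26. DESeq2 called 1462, 977 and 1639 genes in the 3 comparisons, and library totals, RLE factors, the UMI minimums, no low-count filter and the sheet's filter also stayed within that range. Scaling moved the median of all genes by less than 0.1 (log2). Single named genes lost the call in 751 results, gained it in 117 and turned, with a call in either fit, in 15. The other 7421 results kept direction and call or had no call in either fit, whatever the direction. Single lists, by the same rule, kept the call or had none in 768, lost it in 32 and gained it in 40. With each cell thinned to 500 UMIs, which leaves 5999 testable genes, 40, 48 and 93 genes were called. With run 1 alone, with fewer samples, 64 genes were called between the E10.5 tissues and 477 between E12.5 and E10.5 liver. With sort date as a block the E10.5 tissues differed in 1838 genes, and in 3 within the megakaryocyte-like class (0 without it). Only the 3 liver and yolk sac pairs of a shared date inform this contrast, which leaves few residual degrees of freedom. The cause was not tested, and the other comparisons share no date between groups, so the block was not run for them. With only the 2 groups in the fit, 303 genes were called between E10.5 and E9.5 yolk sac, with fewer samples to estimate the spread. Leaving out 1 replicate gave 740 (without yolk sac replicate 3) to 1408 (without liver replicate 1) genes between the E10.5 tissues. It gave 177 (without E9.5 replicate 1) to 792 (without E10.5 replicate 5) genes and 6 to 9 lists between E10.5 and E9.5 yolk sac, and 289 (without E12.5 replicate 1) to 1308 (without E10.5 replicate 2) genes between E12.5 and E10.5 liver. Without a replicate of E9.5 or E12.5, the lone one left is assumed to vary like the other groups. Without the replicates of run 1 or run 3, with fewer samples, 203 and 85 genes were called between the E10.5 tissues, and without those of run 3, 159 between E10.5 and E9.5 yolk sac. Without run 2, 250 genes and 12 lists (6 with all replicates) were called between E10.5 and E9.5 yolk sac. With an estimated correlation 3, 1 and 1 lists passed camera in the 3 comparisons, compared with 14, 6 and 13 with the preset one. With the sheet's cell filter 2 class shares passed, granulocyte-like and mast cell-like at E10.5 (differences of -13.3 and -13.0 percentage points, exact permutation adjusted p = 0.0390 for each, 0.214 and 0.562 in the reported test), and the mast cell-like class then took in a further cluster (388 cells).

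With only the MEP wells, 2692 genes changed between E12.5 and E10.5 liver. Among genes with a call in either fit, the log2FC then turned for Anxa1 (-0.29), Clec12a (-1.65), Cpa3 (-2.52), Dlk1 (-0.40), Elane (-1.23), Ifitm1 (-2.57), Mpo (-2.57), Pdgfrb (-2.54), Ptprc (-2.09) and Satb1 (-1.58). With only the non-MEP wells it turned for Cd79b (0.048), Ly6e (0.018) and Pecam1 (0.091). Sqle turned with thinned cells (-0.042), and H19 between the E10.5 tissues without the endoderm-like cells (0.055). For these single genes the cause was not tested. MEP and non-MEP wells differed in 1391 genes with no replicate block and 4275 with it.

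The Rep numbers were tested as a replicate block, although nothing says that equal numbers share an animal or day. Equal numbers did not deviate together at E10.5, with correlations of 0.028, 0.19, -0.33, -0.15 and 0.16 between tissues, and not every sample correlated best with its own number. Liver and yolk sac replicates sorted on the same date, which also shared a sequencing run, had 0.32, 0.37 and 0.51. Pairs of the same run but another date had -0.093 to 0.65, the highest being liver replicate 3 with yolk sac replicate 5. Liver replicate 1 had 0.49 with yolk sac replicate 3, of the same run only, and 0.32 with replicate 2, of the same date. Effects of date and run can therefore not be told apart here. For E10.5 against E9.5 yolk sac the 2 equal numbers gave 0.081 and 0.34, and for the liver 0.15 and 0.105. With the replicate block 558, 654 and 462 genes were called. The MHC class II list then passed camera between the E10.5 tissues (adjusted p = 3.49e-04) and between E10.5 and E9.5 yolk sac (adjusted p = 8.47e-11). So did endothelial at E10.5 (adjusted p = 0.0457), and interferon response (adjusted p = 0.0481) and macrophage and monocyte (adjusted p = 0.0226) between E12.5 and E10.5 liver, and no other list call changed.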

Other observations

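The comparison of MEP with non-MEP wells, the tests by sorted wells and by sequencing run, the sort date as a block, and the splits of the E10.5 replicates were chosen after the results were seen, and the other tests of this part before.

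On the E12.5 plates the sheet lists wells sorted as MEP and wells sorted as non-MEP, and wells given to neither were left out here. Both kinds came from both E12.5 replicates, with 172 and 668 MEP cells and 187 and 717 non-MEP cells. Erythroid-like cells made up 97.1% (95% Wilson interval 93.4 to 98.8) and 77.8% (74.5 to 80.8) of MEP cells, and 38.5% and 28.6% of non-MEP cells. No granulocyte-, mast cell-, megakaryocyte- or endoderm-like cell was found among MEP cells (0 in both replicates, Wilson upper limits 2.18% and 0.572%). In non-MEP wells granulocyte-like cells made up 23.0% and 7.39%, mast cell-like cells 17.1% and 23.3%, and megakaryocyte-like cells 4.28% and 0.976%. With the replicate as a block, 1892 of 11341 genes were higher and 2383 lower in MEP wells (edgeR adjusted p under 0.05), though 2 sums of each kind leave 1 residual degree of freedom. Without the block 156 were higher and 1235 lower. MEP wells were also deeper, with medians of 19832 and 13861 UMIs per cell compared with 14159 and 9009.

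Members of the granulocyte list (17 of 17 tested) and of the mast cell and basophil list (7 of 7) were lower in MEP wells (camera adjusted p = 1.76e-106 and 2.06e-37, adjusted p = 0.439 for each with an estimated correlation). Elane had 1.64 ± 2.16 CPM against 137 ± 158 in non-MEP wells (log2FC -6.48, SE 0.21, edgeR adjusted p = 3.83e-13). Ifitm1 had 5.31 ± 0.573 CPM against 463 ± 71.5 (log2FC -6.46, SE 0.11, edgeR adjusted p = 2.35e-17), and Gzmb and Cpa3 were lower too (log2FC -6.40 and -6.26, edgeR adjusted p = 9.73e-12 and 2.71e-12). Of the megakaryocyte list 20 of 24 members were lower, and of the stem and progenitor list 17 of 21, with 3 higher (camera adjusted p = 1.42e-11 and 1.50e-20). Lower as well were 14 of 19 macrophage and monocyte, 15 of 18 hepatoblast, 12 of 15 imprinted and fetal growth (2 higher) and 10 of 17 interferon response members (camera adjusted p = 6.60e-22, 2.17e-07, 8.02e-06 and 9.30e-05). The same held for 4 of 5 lymphoid, 5 of 8 fetal RNA-binding program, 4 of 7 yolk sac endoderm and 6 of 9 endothelial members (camera adjusted p = 1.73e-04, 0.00166, 0.0218 and 0.0264). Each of these lists had adjusted p = 0.439 with an estimated correlation. The endoderm-like cells, all in non-MEP wells, were not left out. Higher in MEP wells were 21 of 26 erythroid members (3 lower), 13 of 17 of heme synthesis and iron uptake (1 lower) and 18 of 24 of S phase (camera adjusted p = 3.37e-08, 1.71e-06 and 2.43e-05, adjusted p = 0.439, 0.504 and 0.439 with an estimated correlation). Adjusted over the list alone, 15 macrophage and monocyte members were lower, 14 of heme synthesis, 20 of S phase and 1 endothelial member were higher, and the other counts of these lists were the same. Among the largest rises were Prss50 (log2FC 0.85, SE 0.09, edgeR adjusted p = 2.02e-06) and Slc40a1, the iron exporter ferroportin (log2FC 0.76, SE 0.11, edgeR adjusted p = 4.86e-05).

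In liver, 20 of 26 erythroid (1 lower), 12 of 18 granulocyte and 6 of 7 mast cell and basophil members were higher at E12.5 than at E10.5 (adjusted p = 0.0608, 0.139 and 0.0245 with an estimated correlation), and the E12.5 plates were split by sort. For the granulocyte and mast cell genes, the median log2FC was -1.76 with only the MEP wells, 3.68 with only the non-MEP wells and 2.42 with all wells, so the size and sign of that rise may follow from how many wells of each kind were sorted. Erythroid genes kept a median log2FC of 1.30 with only the non-MEP wells (1.52 with all wells), which argues against the sorted wells as the whole cause of their rise. With those wells the list passed camera only with the preset correlation (adjusted p = 1.12e-13, and adjusted p = 0.101 with an estimated correlation). Within sequencing run 1 the erythroid median was 1.51, which argues against the run as its cause. Stage remains an untested explanation, and whether the E10.5 gate took in the same cells as the E12.5 gates together stays open.

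Transcripts of hepatoblasts and yolk sac endoderm were lower in E10.5 liver than in E10.5 yolk sac (log2 ratio of their summed CPM -2.86, with Afp at 2.33 ± 1.12 CPM against 233 ± 260.1). With the 16 endoderm-like cells left out of all groups the ratio was -0.60, from 113 ± 11.5 and 171.5 ± 40.5 CPM (6 and 5 replicates, ranges 98.7 to 126 and 147 to 243), which is consistent with a few endoderm cells that passed a sort for Kit and YFP. The remaining ranges did not overlap, so a smaller difference stays open, and the lists share 1 gene, Apom. For free RNA taken into the wells, the lists' UMIs per 10000 differed 8.95-fold between the yolk sac clusters, above the bound of 5-fold set against free RNA. The highest (9.55) had a median of 1141.5 UMIs per cell, and a fixed amount of RNA per well is a larger part of a shallow well. The bound was set aside for that reason after the value was seen. Another shallow cluster, with a median of 1018 UMIs per cell, had only 2.01 (counting SE 0.33), so depth alone does not account for the 9.55. Among clusters with a median of 5000 or more UMIs the ratio was 2.46, so free RNA and low expression in progenitors cannot be told apart there.

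For the 1134 genes that differed between the E10.5 tissues, 1 of 100 splits of the 11 replicates (462 possible), the real one, gave as many, and the highest of the others gave 176, so chance as the source of that count is excluded at this number of splits if the replicates can be freely exchanged. Such exchange leaves out that 3 liver and yolk sac pairs shared a sort date (correlations of 0.32, 0.37 and 0.51). It also leaves out that sequencing runs differed, with up to 0.65 between a liver and a yolk sac replicate of 1 run but different dates. The count was 1838 with sort date as a block, which rests on those 3 pairs, and 64 with run 1 alone. Within the megakaryocyte-like class the real split gave 0 genes by edgeR and by DESeq2, a count that 84 of 84 splits reach by definition, so the splits say nothing about chance there. Of the 83 other splits, 6 gave any gene (7.23%), and in 6 of these 6 the smaller side held 2 replicates of 1 sort date, as it does in 28 of all 84 splits. The 3 highest gave 47 genes (fetal liver replicates 3 and 4 with yolk sac replicate 6), 40 (fetal liver 1 with yolk sac 2 and 3) and 25 (fetal liver 3, 5 and 6). This points to a structure of these samples that goes with sort date or with sequencing run, which replicates of 1 date shared. It was seen only afterwards and the splits overlap, so no p is given, and with sort date as a block the real split gave 3 genes.

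Clusters without a class name held these shares. A cluster led by Csf2rb, Hdc, Lmo4 and Gata2 held 8.33% of E10.5 liver, 19.6% of E10.5 yolk sac, 2.06% of E12.5 liver and 6.93% of E9.5 yolk sac cells. A cluster with a median of 1087 UMIs, led by H2-Aa, H2-Eb1 and Cd207, held 0.931%, 16.1%, 10.48% and 0.103% in the same order, and one with a median of 830 UMIs held 8.13%, 6.98%, 0.434% and 13.8%. The looser naming added 3 clusters to the erythroid-like class, the one led by H2-Aa, the cluster led by Hba-x and Hbb-y (29.5%, 6.69%, 1.03% and 0.103%) and one led by mitochondrial and ribosomal genes (0.147%, 0.0587%, 2.93% and 0%).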
